A study of Danio rerio with 6 samples.

How the data were processed

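The deposited files held, per the labels, 1 normalised signal value per gene and library, and the values equalled whole reads divided by a library's DESeq2 size factor, as the authors' processing notes name DESeq2. Per the submitters' processing notes, reads were trimmed with Trim Galore, aligned with STAR 2.6.1d to danRer10 and counted per gene with featureCounts. The versions of Trim Galore, featureCounts and DESeq2, the annotation release, the use of strand in counting and the treatment of reads with several matches were not given in the sources used here. The labels name about 1500 embryos and 10000 GFP-positive cells sorted, RNA extraction with RNeasy Micro kits, SMARTseq2 amplification and single-end reads of 50 nt on a HiSeq 2500. The number of GFP-negative cells was not given in the sources used here. SMARTseq2 libraries carry no molecular identifiers and no strand, so reads are not independent molecules, and genes with antisense neighbours or close copies are uncertain.

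Dividing each column by its smallest step returned whole reads for 100% of values, within 0.01 read, and the implied factors equalled DESeq2 size factors recomputed from those reads. Gene names were those of the files, and 1079 clone names were replaced by the symbol given for the identifier. Of 31953 genes in the files, 6090 had a value of 0 in every library and 26121 identifiers matched the symbol table. Genes with a value of at least 10 in at least 3 libraries, 15971 of them, were tested. The test was limma on log2(value + 1) with group as the only term, a fitted mean-variance trend and robust variance shrinkage, and Benjamini-Hochberg adjusted p under 0.05 made a call. The added 1 understates fold changes of genes with low values. Changes past 2-fold were tested with limma's treat. A call of higher or lower refers to GFP-positive relative to GFP-negative cells. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.

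An edgeR test of counts was planned before the data were examined. The deposited unit led to limma instead, and edgeR with TMM on the recovered reads, which called 1409 genes higher and 54 lower, became an alternative. The 27 gene lists, with 894 entries of which 856 matched, were written from general knowledge of the tissue, and 51 listed genes were on 2 or more lists. Lists with at least 5 tested genes were tested with camera at a preset correlation between genes of 0.01, and again with a correlation estimated from the 6 libraries. Camera asks if a list's genes rank apart from all others, whereas fry, used as an alternative, asks if a list's genes differ at all between groups. Camera called 14 lists higher and 6 lower, and 0 with the estimated correlation, where 3 lists had an unadjusted p under 0.05. The estimate was 0.75, 0.81 and 0.51 for the enveloping layer, desmosome and tight junction lists. Camera's p-values at the preset 0.01 may therefore be far too small for such lists. With the estimate, even the enveloping layer list, with 23 of 28 genes higher, had an unadjusted p of 0.0584 (camera). A missing call there therefore says little against a list.

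Genes were named by rule. The reporter gene came first, then the 12 largest changes in each direction among called genes whose groups did not overlap, with a mean of at least 10 CPM (counts scaled to library size) in the higher group and a name that is not a clone name. Up to 4 members per list were then named, taken from those with the smallest adjusted p and from uncalled members with the highest level. Members of counts of 5 or fewer outside this rule (cers2b, slc3a2a, bcl2l1, bcl2l10, bmp4, dnaaf1 and hes6) were named after their values were seen, which takes some lists past 4 names.

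In a self-test, changes were planted into simulated libraries of 15971 genes. The test found 4% of 2-fold, 54% of 4-fold, 80% of 8-fold and 96% of 16-fold changes, with 10 false calls among 127. The edgeR test found 4%, 54%, 78% and 96%. Small changes were therefore mostly missed in the self-test. It planted 50 genes per fold and made 127 calls, against 1513 in the data, so its adjusted p cut was stricter. Recovery of small changes in the data may be higher than these shares. Genes not called still cannot be read as equal between groups.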

Results

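The enveloping layer (EVL) is the outermost epithelial sheet of the early zebrafish embryo. RNA was sequenced from dissociated Tg(krt18:krt18-GFP) embryos, in which EVL cells carry a GFP-tagged keratin, at 6 hpf (hours after fertilisation), when gastrulation begins. Sorted GFP-positive (EVL) and GFP-negative (non-EVL) cells gave 3 libraries each, and the comparison asked which genes differ between this surface epithelium and the rest of the embryo's cells. The GFP-positive libraries held 32.2M, 38.3M and 34.5M reads assigned to genes, and the GFP-negative libraries held 36.7M, 38.9M and 46.1M. The gene listed as AC024175.4 (ENSDARG00000080337) took between 30.1% and 42.7% of the reads of each library, was higher in GFP-positive cells (log2 fold change 0.55; limma, adjusted p = 0.0311) and left 20.6M to 30.3M reads for all others. Between 20841 and 21827 genes had at least 1 read. Genes with names starting in mt- took at most 1.54% of reads, which leaves out any mitochondrial transcript listed under another name. The sources used here do not say what AC024175.4 encodes. If it is such a transcript, the mitochondrial share is far larger than 1.54%. The first principal component of the log2 values separated the 2 groups and held 60.1% of the variance, and the second held 17.4%. Nothing in the labels says that the libraries came from separate clutches or sorts, so the p-values measure only the spread between these samples, which may be technical.

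The reporter's own gene, krt18 (ENSDARG00000018404), checked the sort. It had 354575 ± 233206 normalised reads in GFP-positive cells and 11380.3 ± 1373 in GFP-negative cells (mean ± SD, n = 3 each), a 27.4-fold rise (log2 fold change 4.78, SE 0.38; limma, Benjamini-Hochberg adjusted p = 0.000647). Reads of the krt18-GFP transgene can be part of that GFP-positive value. The keratins krt4, krt5 and krt8 were 26.5-fold, 26.0-fold and 25.9-fold higher in GFP-positive cells. Over 8 keratins the GFP-negative level was a median 3.25% of the GFP-positive level, with 2.80%, 3.59% and 3.38% in GFP-negative replicates 1, 2 and 3, and the median was 5.32% without GFP-positive replicate 1. In the other direction, the 5 called genes of the mesoderm, endoderm and pluripotency lists that were lower in GFP-positive cells (eve1, hes6, mych, sox2 and sox3) stood at a median 48.0% of their GFP-negative level. That figure was 45.3%, 43.6% and 57.6% in GFP-positive replicates 1, 2 and 3. It does not measure the share of non-EVL RNA in GFP-positive cells, since EVL cells may express these genes themselves, which was not tested. Among other lower genes, szl stood at 22.4% and dnd1 at 5.66% of their GFP-negative level. Keratins and claudins are families of similar genes, so reads of 50 nt could be shared between copies and values of single members are uncertain.

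**Figure D1:**
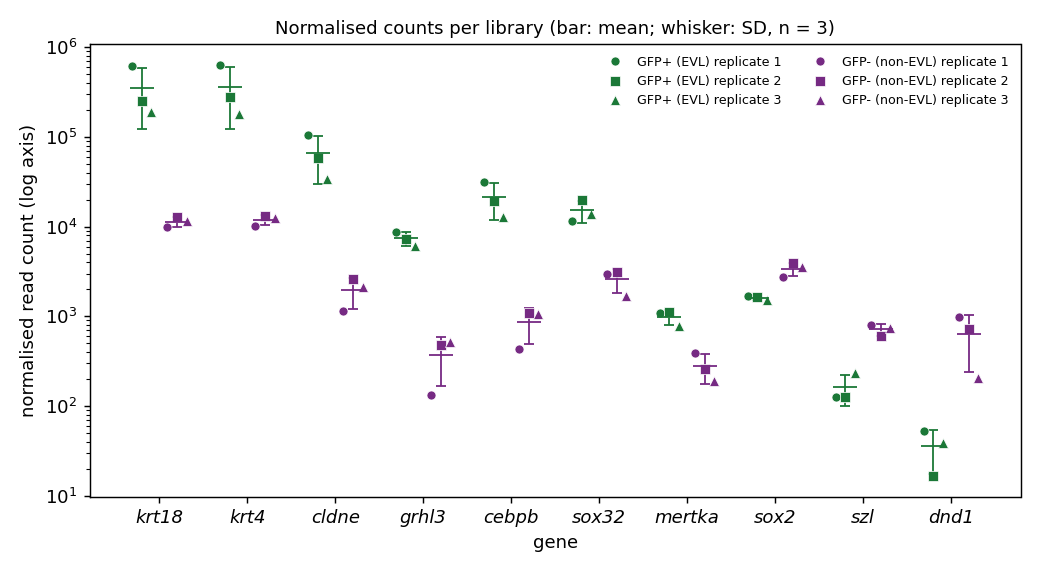
Normalised read counts (log axis) of 10 genes in each of the 6 libraries, with GFP-positive (EVL) libraries in green and GFP-negative (non-EVL) libraries in purple. Horizontal bars are group means and whiskers are the SD (n = 3); krt18 averaged 354575 against 11380.3, whereas dnd1 averaged 35.9 against 634.

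The claudin cldnc rose 53.1-fold (989 ± 637 against 16.9 ± 9.31 normalised reads, n = 3 each; log2 fold change 5.73, SE 0.53; limma, adjusted p = 0.000673). The tricellular junction gene marveld2b rose 41.9-fold and eppk1, which encodes the cytolinker epiplakin, rose 37.5-fold. The NF-kappaB family gene rel rose 47.7-fold and cyba, a subunit of the NADPH oxidase, rose 37.5-fold. The rise of rel leaned on GFP-positive replicate 1 (1397 normalised reads, against 174 in each of the others). Its log2 fold change went from 5.58 to 4.58 without that library. The rel gene was not called in limma-voom (adjusted p = 0.0854). CD109 was 50.4-fold higher, with 0.87, 25.7 and 40.9 normalised reads in GFP-negative replicates 1, 2 and 3. The ratio of its group means was 32.6. The genes slc35d2, adam28, soul2, IL17RD (1 of 2), cldn8.2 and agr1 rose between 37.6-fold and 42.7-fold. Some of these rises also leaned on GFP-positive replicate 1. Replicates 1, 2 and 3 held 1606, 318 and 277 for adam28, 1962, 425 and 273 for IL17RD (1 of 2), and 26436, 4942 and 4564 for agr1. Germ cell genes led in the other direction: dnd1 (ENSDARG00000022813), which protects germ cell transcripts, was 15.8-fold lower in EVL cells (35.9 ± 18.2 against 634 ± 394; log2 fold change -3.98, SE 0.65; limma, adjusted p = 0.00645), nanos3 was 8.87-fold lower and tdrd7a 6.58-fold lower. The ventral BMP pathway gene szl was 4.60-fold lower (limma, adjusted p = 0.00306), the segmentation clock gene her7 3.57-fold lower and alpl 2.99-fold lower. The homeobox genes msxc and eve1 were 3.82-fold and 2.80-fold lower, and foxp2, st8sia1, kazald2 and PPFIBP1 (1 of 2) were 2.37-fold to 2.54-fold lower.

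Of 15971 genes tested, 1405 were higher and 108 lower in EVL cells at an adjusted p under 0.05 (limma, Benjamini-Hochberg), so 92.9% of the called genes were higher. With libraries scaled to their size alone, edgeR called 1253 higher and 930 lower, a share of 57.4%. The higher genes had a median fold of 11.9 and the lower genes a median fold of 1.86. Past a 2-fold minimum (limma's treat), 741 genes were higher and 2, dnd1 and szl, were lower. The 3 libraries of each group did not overlap in 4941 genes (30.9%, where chance gives 10%). GFP-positive replicate 1 had the highest value of the 3 GFP-positive libraries in 666 of the 741 genes, with a median 1.92 times the level of replicate 2 and 2.89 times that of replicate 3. Without that library 1025 genes were higher, 40 were lower and 522 were higher past the 2-fold minimum.

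Leaving out any single library shortened the list of lower genes. It held 42 and 77 genes without GFP-positive replicates 2 and 3, and 50, 14 and 22 without GFP-negative replicates 1, 2 and 3. The genes lower past the 2-fold minimum were 4 without GFP-positive replicate 1, 1 without GFP-positive replicate 2 and 0 without GFP-negative replicate 1 or 2, where treat gave 33 and 16 at an unadjusted p under 0.05. The call of CD109 was lost without GFP-positive replicate 1 (limma adjusted p = 0.0560) or 2 (0.0589), that of nanos3 without GFP-negative replicate 2 (0.0568), and that of tdrd7a without GFP-positive replicate 1 (0.0669) or 3 (0.0525) or GFP-negative replicate 2 (0.0733). Each of msxc, eve1, foxp2, st8sia1, kazald2 and PPFIBP1 (1 of 2) lost its call without GFP-negative replicate 3 (adjusted p from 0.0552 to 0.172), and all of these except kazald2 also without GFP-positive replicate 2 (0.0519 to 0.0949). The call was also lost without GFP-negative replicate 2 for msxc, eve1, foxp2 and PPFIBP1 (1 of 2) (0.0566 to 0.175), without GFP-positive replicate 1 for the same 4 genes (0.0504 to 0.0979), without GFP-negative replicate 1 for msxc, st8sia1 and PPFIBP1 (1 of 2) (0.0586 to 0.0991), and without GFP-positive replicate 3 for foxp2 (0.0866).

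Markers of the enveloping layer and of the later periderm rose together. Of 28 tested, 23 were higher and 0 lower in GFP-positive cells (25 and 0 adjusted over the list alone), with a median log2 fold change of 4.79 (camera, adjusted p = 1.54e-25; adjusted p = 0.288 with an estimated correlation). Desmosome and hemidesmosome genes were higher in 13 of 15 (14 adjusted over the list alone), among them pkp3a, a plakophilin (log2 fold change 4.58), and the plakin family genes ppl (4.92), evpla (5.16) and pleca (4.39). Their median was 4.58 (camera, adjusted p = 1.85e-17; adjusted p = 0.288 with an estimated correlation). Tight junction genes were higher in 17 of 27, with 0 lower (18 and 1 adjusted over the list alone), among them cldnc, given above, and the claudins cldnb (35.4-fold), cldne (32.1-fold) and cldnf (31.6-fold), and their median was 2.93 (camera, adjusted p = 3.90e-13; adjusted p = 0.288 with an estimated correlation). The tight junction plaque gene tjp2a was not called (log2 fold change 0.35, limma, adjusted p = 0.260). Of 11 adherens junction genes, epcam (3.17) and cdh1, which encodes E-cadherin (2.16), were higher (3 adjusted over the list alone), while the catenin gene ctnnb1 stood at -0.33 (limma, adjusted p = 0.289). Camera did not call the list (adjusted p = 0.0941; adjusted p = 0.290 with an estimated correlation), whereas fry did (higher, adjusted p = 0.0384).

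Transcription factors of the surface epithelium were higher in 15 of 26 and lower in 1 (16 and 2 adjusted over the list alone), with a median log2 fold change of 2.33 (camera, adjusted p = 5.45e-09; adjusted p = 0.288 with an estimated correlation). The epidermal regulators znf750 (4.56) and grhl3 (4.50) and the basic leucine zipper gene cebpb (4.64) rose over 20-fold, from 58.7, 375 and 857 normalised reads in GFP-negative cells. klf17, a Krueppel-like factor, rose 6.54-fold, from 1282 ± 144 to 8526 ± 2044 reads (n = 3 each). The lower gene was the AP-2 family gene tfap2c (log2 fold change -1.04, limma, adjusted p = 0.00598). Genes of lipid, ceramide and barrier metabolism were higher in 13 of 32 and lower in 1 (16 and 2 adjusted over the list alone; median 0.90; camera, adjusted p = 4.20e-06; adjusted p = 0.288 with an estimated correlation). The sphingolipid enzymes degs2 (4.67) and sptlc3 (3.80), the fatty acid elongase elovl1a (4.61) and the lipoxygenase alox12 (4.50) rose, and the ceramide synthase cers2b fell by 0.97 on the log2 scale. The call of cers2b was absent without each library except GFP-positive replicate 3, since the count of lower genes on the list was 0 in those 5 fits.

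Genes of the actin cytoskeleton were higher in 10 of 51, with 0 lower (15 and 1 adjusted over the list alone). They included profilin pfn1 (68122 ± 46155 against 3411 ± 728 normalised reads, n = 3 each; log2 fold change 4.14), the calponin cnn2 (3.36), the transgelin tagln2 (3.33) and waslb (3.72), an activator of branched actin assembly. The list's median was 0.38 (camera, adjusted p = 0.000550; adjusted p = 0.300 with an estimated correlation). Of 34 genes for extracellular matrix and integrins, 7 were higher and 0 lower (8 and 1 adjusted over the list alone), with the hyaluronan receptor cd44a (4.58), the laminin lama5 (2.84), the collagen col4a5 (2.57) and the protease inhibitor timp2b (3.78) among them. The list had a median of 0.20 (camera, adjusted p = 0.0466; adjusted p = 0.300 with an estimated correlation), which moved to -0.22 with library size alone and -0.077 with upper quartile scaling. These scalings moved the median of all genes to -0.37 and -0.24, and camera still called the list higher (adjusted p = 0.0421 and 0.0488). Of 21 genes for ion, water and solute transport, 5 were higher and 0 lower (5 and 0 adjusted over the list alone): the water channel aqp3a (4.46), the chloride channel cftr (3.91) and the amino acid transporter genes slc7a5 (4.57), slc3a2b (3.48) and slc3a2a (2.49). That list's median of 0.29 (camera, adjusted p = 0.0466; adjusted p = 0.288 with an estimated correlation) moved to -0.0014 with library size alone, where camera still called it higher (adjusted p = 0.0421). Without GFP-positive replicate 2 or 3, the matrix list lost its call (limma's camera, adjusted p = 0.0773 and 0.0687) and 4 of its genes were higher; without GFP-negative replicate 2 or 3 the adjusted p was 0.115 and 0.0853. The transport list lost its call without GFP-positive replicate 2 or 3 (0.140 and 0.0610) or GFP-negative replicate 1 or 3 (0.0948 and 0.0507). Both lists also lost their calls in edgeR with DESeq2 size factors (0.0791 for matrix and 0.0611 for transport) or TMM (0.0931 and 0.0631) and with a minimum of 5 CPM (0.135 and 0.168), and the matrix list with DESeq2 (0.0857).

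**Figure D2:**
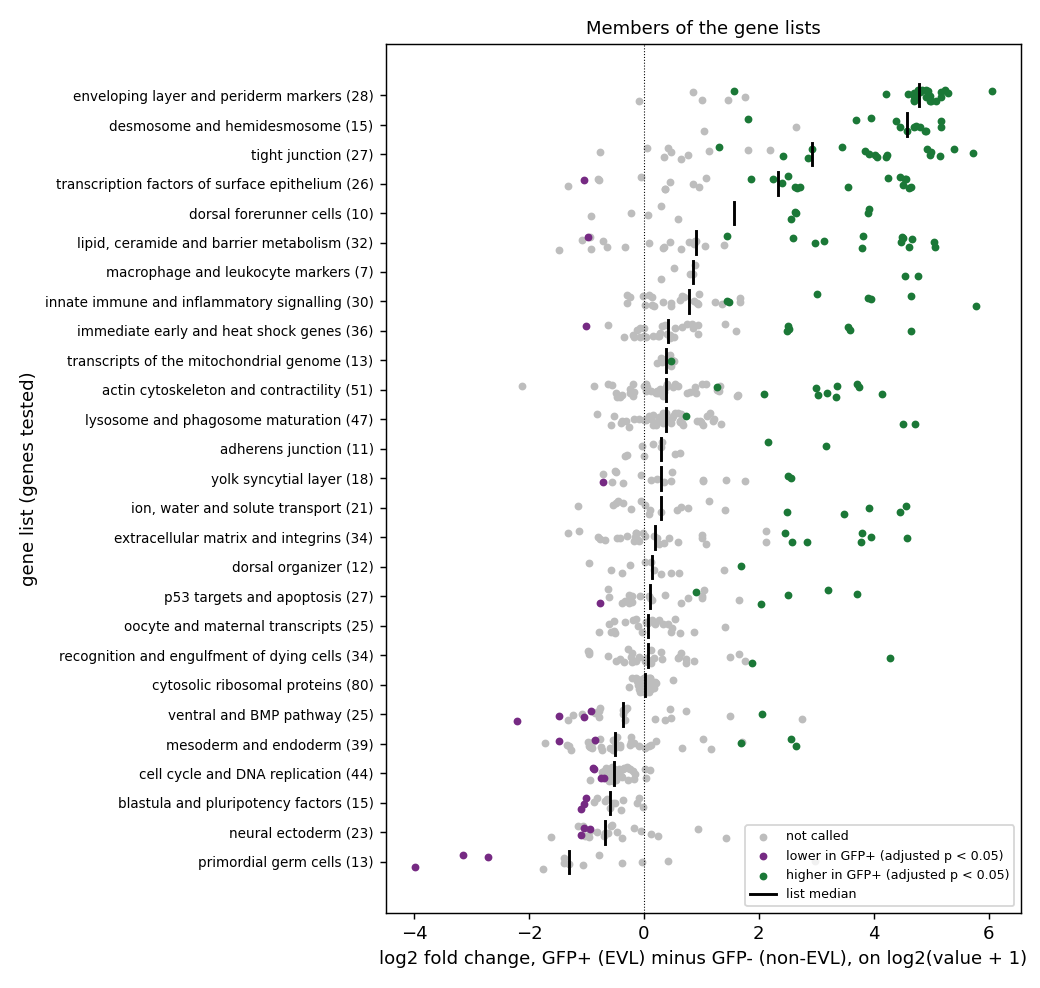
Log2 fold change (GFP-positive minus GFP-negative cells) of each tested member of the 27 gene lists, with the number tested in brackets. Each point is a gene, green and purple points passed the test as higher or lower, grey points did not, and black bars are list medians, which run from -1.30 for primordial germ cell genes to 4.79 for enveloping layer and periderm markers. With library size alone 10 of the medians above 0 fell below it, as that scaling moved the median of all genes from -0.057 to -0.37.

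Among 34 tested genes for the recognition and engulfment of dying cells, 2 were higher and 0 lower in EVL cells (1 and 0 adjusted over the list alone). These were mertka, a receptor for bridged phosphatidylserine, with 995 ± 187 against 278 ± 101 normalised reads (n = 3 each; log2 fold change 1.88, SE 0.31; limma, adjusted p = 0.00627), and megf10, an engulfment receptor, with 92.9 ± 64.9 against 4.83 ± 5.64 reads (4.29, SE 1.04; limma, adjusted p = 0.0385). The GTPase genes rac1a (0.12, adjusted p = 0.723) and cdc42l (0.74, adjusted p = 0.0853) were expressed in both groups and not called, and the list did not stand apart (median 0.070; camera, adjusted p = 0.608; adjusted p = 0.743 with an estimated correlation). Its median turned to -0.25, -0.14 and -0.097 with library size alone, upper quartile scaling and scaling to the total outside the most abundant gene. The call of megf10 was lost without GFP-positive replicate 1 (0.139) or 2 (0.119) or GFP-negative replicate 1 (0.0718) or 3 (0.0885), which left 1 higher gene on the list in each of these fits. The log2 fold change of megf10 in these fits was 3.75, 4.07, 4.41 and 3.33, in that order. Without GFP-negative replicate 2 the list had 3. It had 2 higher and 2 lower in edgeR with library size alone, and 5 higher and 1 lower in DESeq2.

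Genes of lysosomes and phagosome maturation were higher in 3 of 47 (2 adjusted over the list alone), with 0 lower in either count, and the median was 0.38 (camera, adjusted p = 0.0137; adjusted p = 0.300 with an estimated correlation). Over all tested genes 8.80% were called higher, a larger share than on this list or on the engulfment list. The genes rab25a (4.72) and rab25b (4.50) encode GTPases of epithelial recycling endosomes, and atp6v1g1 (0.73) a subunit of the proton pump. The lysosomal cathepsin gene ctsla was not called (-0.17, limma, adjusted p = 0.717). In edgeR with library size alone 2 genes of this list were higher and 2 lower, and in DESeq2 6 were higher and 0 lower. The call of atp6v1g1 was lost without any of the 6 libraries (0.0583 to 0.139). Of 18 macrophage and leukocyte genes 11 were below the minimum level, including spi1b, mpeg1.1 and csf1ra. Of the 7 tested, lcp1, an actin bundling gene, and lmo2 were 27.4-fold and 23.3-fold higher and 0 were lower (2 and 0 adjusted over the list alone; median 0.86; camera, adjusted p = 0.0105; adjusted p = 0.288 with an estimated correlation), and the oxidase gene cybb was not called (0.31, adjusted p = 0.634).

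Innate immune and inflammatory genes were higher in 7 of 30, with 0 lower (10 and 0 adjusted over the list alone; median 0.79; camera, adjusted p = 0.000108; adjusted p = 0.288 with an estimated correlation). The interferon pathway genes stat1b (log2 fold change 5.79), mxa (3.95) and irf2 (3.02) and the cytokine gene tnfb (4.65) rose. Levels of stat1b, mxa and irf2 were low, with means of 224, 374 and 119 normalised reads against 4.60, 22.3 and 12.5 in GFP-negative cells. The stat1b gene had 9.56, 0 and 4.23 in GFP-negative replicates 1, 2 and 3, so the size of its rise is uncertain. In tnfb the mean was 2372 ± 2869 normalised reads against 52.5 ± 9.75 (n = 3 each). GFP-positive replicates 1, 2 and 3 had 5661, 1069.5 and 385. The tnfb gene was not called in limma-voom (adjusted p = 0.0799). Immediate early and heat shock genes were higher in 6 of 36 and lower in 1 (6 and 1 adjusted over the list alone; median 0.43; camera, adjusted p = 0.0137; adjusted p = 0.316 with an estimated correlation). Of these cebpb (4.64), klf6a (3.56) and gadd45ba (2.51) rose and the Myc family gene mych fell by 1.01 on the log2 scale. This median moved to -0.040 with library size alone, where camera still called the list higher (adjusted p = 0.0348). The list lost its call without GFP-negative replicate 2 or 3 (0.0673 and 0.0675), and mych lost its call without GFP-negative replicate 2 (0.0527). Of 27 genes for p53 targets and apoptosis, 5 were higher and 1 lower (7 and 2 adjusted over the list alone), namely gadd45aa (log2 fold change 3.70), baxb (9.18-fold), gadd45ba (5.68-fold), badb (4.13-fold) and bcl2l1 (1.87-fold) against bcl2l10 (1.70-fold lower). Camera did not call the list (adjusted p = 0.132; adjusted p = 0.300 with an estimated correlation), whereas fry did (higher, adjusted p = 0.0274). The median of 0.11 turned to -0.16 with library size alone. It turned to -0.035 with upper quartile scaling, -0.055 with scaling to the total outside the most abundant gene and -0.0033 without GFP-negative replicate 3. The higher genes of that list were 3 without GFP-positive replicate 2 or GFP-negative replicate 2, bcl2l10 lost its call on leaving out each of the 6 libraries in turn, and badb lost its call without GFP-positive replicate 2 or GFP-negative replicate 1, 2 or 3 (0.0609 to 0.0773).

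Dorsal forerunner cells later form the left-right organiser. Of 10 marker genes tested, 5 were higher in GFP-positive cells and 0 lower (6 and 1 adjusted over the list alone; median 1.58; camera, adjusted p = 0.00134; adjusted p = 0.288 with an estimated correlation). The endoderm and forerunner regulators sox32 (15172 ± 4319 against 2603 ± 799 normalised reads, n = 3 each) and sox17 rose 5.89-fold and 6.28-fold, the cilium regulator foxj1a 15.0-fold, cftr 15.1-fold, and dnaaf1, a cilium assembly gene, by 2.64 on the log2 scale. The mesoderm gene ta, which forerunner cells also express, was not called (-0.92, limma, adjusted p = 0.127), but was called lower without GFP-positive replicate 3 (0.0347). Of 39 mesoderm and endoderm genes, sox32, sox17 and foxa2 (1.69) were higher and eve1 (-1.48) and hes6 (-0.86) lower (3 and 2 adjusted over the list alone). That list's median was -0.50 (camera, adjusted p = 0.0466; adjusted p = 0.582 with an estimated correlation). It lost its call without GFP-positive replicate 1 (0.576) or GFP-negative replicate 1, 2 or 3 (0.0698, 0.0673 and 0.0517). The list's median was -0.025 in the first of these fits and -0.38, -0.48 and -0.52 in the others. The call was also lost in edgeR with DESeq2 size factors (0.0726), library size alone (0.218), upper quartile (0.137) or TMM (0.0572), with DESeq2 (0.143), limma-voom (0.120), limma with TMM (0.0508) or the total outside the most abundant gene (0.0840), with a minimum of 5 CPM (0.196), and with fry (0.569). Its lower genes were 0 without GFP-positive replicate 1 or 2 or GFP-negative replicate 2 or 3, 1 without GFP-negative replicate 1 and 4 without GFP-positive replicate 3. In those first 4 fits eve1 lost its call (adjusted p 0.0834, 0.0943, 0.150 and 0.144).

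Of 12 dorsal organizer genes 1, foxa2, was higher and 0 lower (1 and 0 adjusted over the list alone; median 0.15; camera, adjusted p = 0.661; adjusted p = 0.839 with an estimated correlation), and chd, which encodes the BMP antagonist chordin, stood at -0.23 (adjusted p = 0.733). The call of foxa2 was lost without GFP-negative replicate 2 (0.0708) or 3 (0.0667). That median turned to -0.042 with library size alone, -0.020 with scaling to the total outside the most abundant gene, and -0.020 without GFP-positive replicate 3. Of 18 genes of the yolk syncytial layer, the neighbouring tissue at the yolk surface, tfa (2.51) and sox32 were higher and the apolipoprotein gene apoeb was lower (-0.70), giving 2 and 1 in both counts, the second adjusted over the list alone (median 0.29; camera, adjusted p = 0.456; adjusted p = 0.620 with an estimated correlation; fry, higher, adjusted p = 0.0375). This median turned to -0.15 with library size alone and -0.030 with upper quartile scaling. The apoeb gene lost its call without GFP-negative replicate 1 (0.0572) or 2 (0.0952).

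Germ cell genes were lower in 3 of 13, dnd1, nanos3 and tdrd7a, with 0 higher (5 and 1 adjusted over the list alone; median -1.30; camera, adjusted p = 0.00171; adjusted p = 0.288 with an estimated correlation). Their levels varied between GFP-negative libraries, with dnd1 at 981, 717 and 206 normalised reads in replicates 1, 2 and 3, and 1 of the 3 calls remained without GFP-negative replicate 2. In limma-voom 0 of the 3 were called (adjusted p = 0.0527 for dnd1 and 0.0814 for tdrd7a). The germ plasm gene ddx4 did not differ detectably (2426 ± 1020 against 2474 ± 1051, n = 3 each; limma, adjusted p = 0.978). Blastula and pluripotency factors were lower in 3 of 15, with 0 higher (4 and 0 adjusted over the list alone): sox2 (log2 fold change -1.05, limma, adjusted p = 0.00742), mych (-1.01) and sox3 (-1.09). Their median was -0.60 (camera, adjusted p = 6.63e-05; adjusted p = 0.290 with an estimated correlation), and pou5f3 stood at -0.39 (adjusted p = 0.693). Of 23 neural ectoderm genes, 3 were lower, sox2 and sox3 among them, and 0 higher (3 and 0 adjusted over the list alone; median -0.67; camera, adjusted p = 0.00249; adjusted p = 0.288 with an estimated correlation). sox3 lost its call without GFP-positive replicate 1 or 2 or GFP-negative replicate 2 or 3 (0.0881, 0.0895, 0.129 and 0.123) and mych without GFP-negative replicate 2 (0.0527). The lower genes were then 1 on the pluripotency list without GFP-negative replicate 2 and 1 on the neural list without GFP-negative replicate 2 or 3.

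Ventral and BMP pathway genes were lower in 4 of 25, szl (-2.20), eve1 (-1.48), tfap2c (-1.04) and bmp4 (-0.91), and higher in 1, the BMP target id2b (2.06), with 6 lower and 2 higher adjusted over the list alone. The median was -0.36 (camera, adjusted p = 0.0167; adjusted p = 0.300 with an estimated correlation). The list lost its call without GFP-positive replicate 2 (0.0502) or GFP-negative replicate 3 (0.0612). It had 2 lower genes without GFP-positive replicate 1 or 2 or GFP-negative replicate 2 or 3, and id2b lost its call without GFP-positive replicate 3 (0.0524) or GFP-negative replicate 3 (0.0510). Of 44 cell cycle and replication genes tested, 4 were lower and 0 higher (6 and 0 adjusted over the list alone), the replication genes mcm5 (-0.89; 4382 ± 582 against 8158 ± 1431 normalised reads, n = 3 each), mcm2 (-0.86), mcm3 (-0.75) and pcna (-0.70), and 3 of the 44 fold changes lay above 0. The median was -0.52 (camera, adjusted p = 4.09e-10; adjusted p = 0.290 with an estimated correlation; fry, adjusted p = 0.0548). The lower genes of this list were 2, 3 and 0 without GFP-positive replicates 1, 2 and 3 and 1, 0 and 2 without GFP-negative replicates 1, 2 and 3, with adjusted p of mcm5, mcm2, mcm3 and pcna rising to at most 0.0877, 0.0624, 0.179 and 0.148. At an unadjusted p under 0.05, limma gave 22 lower and 0 higher, and edgeR with library size alone called 20 lower.

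Cytosolic ribosomal protein genes did not differ detectably: limma called 0 of 80 (0 adjusted over the list alone and 0 at an unadjusted p under 0.05; edgeR and DESeq2 also called 0), with rps2 at 28835 ± 5342 against 29214 ± 7414 normalised reads (n = 3 each). Oocyte and maternal transcripts gave 0 of 25 called in limma (0 adjusted over the list alone), with 1 lower at an unadjusted p under 0.05 and 2 lower in edgeR with library size alone, and ybx1 stood at 0.075 (adjusted p = 0.768). In both lists the median (0.017 and 0.075) and mean (0.021 and 0.071) lay above 0 while camera's direction was down (adjusted p = 0.803 and 0.828; adjusted p = 0.966 for both with an estimated correlation). With library size alone these medians turned to -0.28 and -0.40, where the median of all genes was -0.37. The ribosomal list was called down without GFP-positive replicate 1 (median -0.14; limma's camera, adjusted p = 0.00210) or GFP-negative replicate 3 (-0.13, 0.00765) and up without GFP-positive replicate 2 (0.22, 0.00284), and the maternal list was called down without GFP-negative replicate 1 (-0.25, 0.0306). Transcripts of the mitochondrial genome, here those with names starting in mt-, were all on the higher side, 13 of 13. The gene mt-co2 was called (log2 fold change 0.48, limma, adjusted p = 0.0417), and 8 were called adjusted over the list alone, with 0 lower. The list's median was 0.39 (camera, adjusted p = 0.000302; adjusted p = 0.300 with an estimated correlation). The call of mt-co2 was lost without any library except GFP-positive replicate 1 (0.0975 to 0.140).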

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

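At an adjusted p under 0.05, more genes were higher than lower in EVL cells in every setting, and no called gene changed sign. At an unadjusted p under 0.05, limma gave 2528 higher and 1150 lower. There edgeR gave 1934 higher and 3417 lower with library size alone, and 2173 and 2068 with upper quartile. The number of genes called lower depended on scaling and test. Against 108 lower genes, edgeR gave 65 with DESeq2 size factors, 930 with library size alone, 185 with upper quartile and 54 with TMM, DESeq2 gave 327, limma-voom 41, and limma scaled to the total outside the most abundant gene 173. The cause was not tested. Leaving out 1 library gave 14 (without GFP-negative replicate 2) to 77 (without GFP-positive replicate 3). Against 1405 higher genes, a minimum of 5 CPM gave 854, from fewer genes tested. Lower genes past the 2-fold minimum, 2 in number, were 4 with DESeq2 size factors in edgeR, 6 with library size alone, 5 with upper quartile, 4 with DESeq2, 0 with limma-voom (19 at an unadjusted p under 0.05), and 1 each with pseudocounts of 0.5 and 10 and with TMM in limma, and ranged from 0 to 4 on leaving out 1 library. The higher genes past that minimum ranged from 495 to 1027 over all settings. Of the lists, 14 higher and 6 lower, camera with an estimated correlation called 0 in each direction, while fry called 16 higher and 1 lower. Lists that fry did not call were the immediate early (adjusted p = 0.0976), pluripotency (0.0794), neural (0.158), ventral (0.158), cell cycle (0.0548) and mesoderm and endoderm (0.569) lists. It did call the adherens (0.0384), p53 (0.0274) and yolk syncytial (0.0375) lists, which camera did not call. Calls were also lost with library size alone (where 20 cell cycle and 6 pluripotency genes were lower) for the mitochondrial (0.0656), lysosome (0.0611) and ventral (0.0705) lists, with DESeq2 for the lysosome list (0.0816), and with genes of at least 1 read for the leukocyte list (0.0572). The ribosomal list's median was -0.14 without GFP-positive replicate 1 and reversed to 0.22 without GFP-positive replicate 2 (camera, adjusted p = 0.00284). The keratin level in GFP-negative cells, 3.25%, ranged from 2.61% without GFP-positive replicate 3 to 5.32% without GFP-positive replicate 1. With the replicate number as a replicate block, 1573 genes were higher and 279 lower. Lower genes were then 15 on the cell cycle list and 6 on the germ cell list. They were 8 each on the pluripotency, neural, and mesoderm and endoderm lists. The matrix and transport lists lost their calls (camera, adjusted p = 0.0526 and 0.131). Deviations from group means correlated at 0.26, 0.33 and 0.07 for equal numbers, and at -0.27 to -0.017 for unequal numbers. Deviations sum to 0 within each group, so values above 0 for equal numbers push those for unequal numbers below 0. The contrast is therefore partly arithmetic. Variation may still be shared by number, and the main fit leaves any such variation in its error. The labels name no pairs, so the block stayed an alternative. The main limma test was chosen once the unit of the deposited values was known, and edgeR with TMM, planned as the main test, then became an alternative. The pseudocounts, TMM in limma and the total outside the most abundant gene were added after the data were seen. The other alternatives were chosen before. With 3 libraries per group and 20.6M to 30.3M reads outside the most abundant gene, changes under 4-fold and genes of low level may often have been missed.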

Other observations

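The tests in this part were chosen after seeing the result, except the regrouping of libraries, which was written before. Of the 10 ways to split the 6 libraries into 3 and 3, 1 called as many genes as the real grouping: the real split itself with 1513, while the highest of the others called 0 (limma). With 10 splits this design cannot go under a share of 0.05. Mixed splits also place the difference in genes such as krt18, cldne and grhl3 within their groups, so few calls there were likely from the start, and the regrouping does not tell.

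EVL transcripts were present at a few percent in GFP-negative libraries, with krt18 at 3.21% and krt4 at 3.29% of the GFP-positive level. This may be RNA or cells of the EVL carried into the GFP-negative sort: of 372 abundant EVL genes, 0% lay below 1.62%, which is 0.5 of the keratin median, and the lowest stood at 1.89%. A floor under these abundant genes could come from carry-over. Of all 741 genes past the 2-fold minimum, 30 (4.05%) lay below that level. These all had GFP-positive means under 1000 normalised reads, the cut for abundant genes. Their GFP-negative values, such as 6.70 for rel, were too low to tell if a floor holds for them. Carry-over between cells of the same replicate number was not settled, since same-number correlations averaged 0.196 against at most 0.0941 in the other 5 of 6 pairings. EVL cells with GFP below the sort gate would give the same floor. Microscopy or in situ staining of krt18 in sorted GFP-negative cells would tell EVL cells from free RNA. Staining alone would not tell carried cells from cells below the gate.

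EVL genes stood higher in GFP-positive replicate 1 than in the others, by a median 2.89 times over replicate 3. A larger share of non-EVL RNA in replicate 3 could give this, and would put genes lower in EVL cells at 65.4% or more of their GFP-negative level in that library. The 77 genes called lower without it stood at a median 64.1%, with an upper quartile of 72.6% and 33 at or above the bound, which does not decide. Against a uniform admixture of that size, alpl and szl stood at 34.4% and 32.3% there, and replicate 2, with EVL genes at 52.1% of replicate 1, held sox2, sox3, mych, eve1 and hes6 at a median 43.6% of their GFP-negative level, against 45.3% in replicate 1. Stage differences between sorts stay open, and counts of non-EVL cells in each sorted fraction would test the admixture.

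Far more genes were called higher than lower in EVL cells at an adjusted p under 0.05. Scaling could account for part of this: limma's share of higher calls was 92.9%, and within edgeR it went from 95.3% with DESeq2 size factors to 57.4% with library size alone, as lower calls went from 65 to 930 and higher calls from 1321 to 1253. Past the 2-fold minimum, the share was at least 99.2% in all 6 other scalings, against 99.7% in the main fit. These scalings moved the median log2 fold change of all genes no further than -0.37, so they could carry few genes across that minimum. The stable share therefore does not rule out scaling as a cause. Lower genes past the minimum at an unadjusted p under 0.05 were 40 in edgeR with DESeq2 size factors and 95 with library size alone. Non-EVL cells among the GFP-positive cells could hide genes absent from the EVL, but 4 genes (dnd1, nanos3, tdrd7a and szl) stood below 27.1% of their GFP-negative level, 0.5 of the median of lower genes, where none was predicted with such cells and 5 or more without, so this stays undecided. The mixture of many cell types in the GFP-negative group may also dilute genes of each type, and single-cell counts at 6 hpf would test this.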
